A study of Rattus norvegicus with 9 samples.

How the data were processed

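Gene expression was measured in kidneys of Sprague-Dawley rats given vehicle, 25 or 50 mg/kg CMS daily for 7 days, with 3 rats and 3 arrays per dose. Per the labels' protocols, the whole right kidney was frozen, total RNA was purified with a kit, its integrity was measured, and biotin-labelled RNA was hybridised to Affymetrix rat 3′ expression arrays. Per the submitters' processing notes, the deposited log2 values came from RMA in Affymetrix Expression Console, with versions not given in the sources used here. RMA corrects the background, makes the distributions of the arrays alike by quantiles and summarises the probes of a probe set, so a shift of all genes in one direction cannot be seen and small changes of dim probe sets are compressed. The values were used as deposited and not normalised again. The value table held 31099 probe sets on 9 arrays with 0 missing values and no unused sample column.

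Gene names came from the platform annotation supplied with the data, which is an older release, checked against a current gene table of the rat assembly GRCr8 that was used for names only. Of 31042 probe sets that are not controls, 20826 had 1 gene symbol, 436 had several and 9780 were not listed with a gene. Of the 20826, 20758 had a gene identifier in the current table, and 0 symbols needed an update. Probe sets with several genes named none. For each of 14217 genes, the probe set with the highest mean over the 9 arrays was used, and genes with a mean log2 value under 5 were left out, which left 10337. The other probe sets of a gene can disagree: of 926 further probe sets of 728 called genes in the CMS50 comparison, 768 changed in the same direction. No genome positions are given, because no build was named for the files.

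The 3 groups were fitted together with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, without trend or robust fitting), which share 1 estimate of the spread per gene. Contrasts were CMS25 minus vehicle, CMS50 minus vehicle, CMS50 minus CMS25, an F test of any dose, and CMS50 minus 2 times CMS25 plus vehicle. P-values were adjusted by Benjamini-Hochberg over all genes tested, genes were called at an adjusted p under 0.05, and a 2-fold change is a log2 difference of at least 1. Intervals are 95% intervals of the fit. Of 37 gene lists for kidney cell types, responses and sample quality, 32 had at least 5 measured genes and were tested with camera at a preset inter-gene correlation of 0.01. Camera with an estimated correlation and fry, a rotation test, were alternatives. The lists, tests, alternatives and named genes were fixed before the data were examined, except where stated. Genes named without a further remark were the 10 largest rises and falls among called genes with non-overlapping arrays at CMS50 against vehicle, 5 and 5 in the other comparisons, up to 4 called members of each called list, and a panel of 13 genes. In any such count, 3 against 3 arrays fail to overlap by chance in 10% of genes. RNA quality was read from the 3′ and 5′ control probe sets for beta-actin and GAPDH. Labels give no batch, hybridisation day or time of kill, so none could be tested.

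Effects that share arrays were set beside 100 simulated draws of unchanged groups, and 3 vehicle arrays are too few to split into sets of at least 2. The fit was tested on simulated data made from the measured means and spreads of the 10337 genes, with 67 genes changed by 0.5 on the log2 scale, 67 by 1 and 66 by 2 in each comparison. For CMS50 minus vehicle, 34.3% of genes changed by 0.5 were recovered, 83.6% of those changed by 1 and 95.5% of those changed by 2, and 2.07% of calls were false. For CMS25 minus vehicle the shares were 38.8%, 88.1% and 95.5% with 7.50% false calls, and for CMS50 minus CMS25 they were 56.7%, 85.1% and 98.5% with 4.19% false. With no gene changed, 0 genes were called in each comparison, and 0 of 32 lists in CMS50 minus vehicle, where alone lists were simulated. Simulated genes varied independently of each other, whereas the correlation estimated within lists reached 0.659 for MHC class II. The simulated list count therefore does not test lists of correlated genes. Alternatives changed the scaling, the intensity minimum, the probe set rule, the variance model, array weights, the arrays fitted and the replicate block, tested each probe set, and left out each array in turn. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.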

Results

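Kidney RNA was profiled in 9 Sprague-Dawley rats, an outbred laboratory stock, after daily intraperitoneal injections for 7 days. The injections held saline vehicle or colistin methanesulfonate sodium (CMS), the prodrug of the polymyxin antibiotic colistin, at 25 or 50 mg/kg. Each dose had 3 rats, named vehicle, CMS25 and CMS50 here, and the labels describe the arrays of a dose as biological replicates. The labels give no lesion for vehicle kidneys, basophilic and dilated tubules for CMS25, and necrosis, tubular degeneration and casts for CMS50. RNA from the whole right kidney was hybridised to Affymetrix rat expression arrays, 1 array per rat, and the deposited values are log2 intensities. For arrays, the number of rats limits the precision. A total of 10337 genes passed the intensity minimum, and the highest correlation between any pair of arrays was 0.989. Group values are means ± SD with n = 3, changes are log2 differences with their standard error (SE), and adjusted p-values come from limma with Benjamini-Hochberg adjustment.

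The first comparison asked what the higher dose changed in the kidney. CMS50 kidneys carried far more RNA of tubular injury genes than vehicle kidneys. Havcr1 (probe set 1387965_at), which encodes the kidney injury molecule shed by damaged proximal tubules, was 79.8-fold higher, at 11.15 ± 0.84 against 4.83 ± 0.81 (log2 change 6.32, SE 0.46, adjusted p = 0.000389). Where a group's mean lies below the intensity minimum of 5, as here, the signal is dim and the fold is approximate. Ubd, a ubiquitin-like modifier induced by inflammatory cytokines, was 50.3-fold higher (log2 change 5.65, SE 0.87, adjusted p = 0.00327), and its log2 change was 6.72 without vehicle replicate 2, 5.06 without vehicle replicate 3 and 6.30 without CMS50 replicate 2. Lcn2 (neutrophil gelatinase-associated lipocalin) rose 24.5-fold, Clu (clusterin) 12.7-fold and Spp1 (osteopontin) 12.5-fold. Gpx2, a glutathione peroxidase, Gpnmb, a glycoprotein of phagocytic cells, Adamts1, a matrix protease, Akr1b8, an aldo-keto reductase, and Cfi, a complement inhibitor, completed the 10 largest rises. Their log2 changes were 3.52, 3.49, 3.39, 3.29 and 3.28.

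The 10 largest falls included 3 genes of tissue kallikreins. Klk1c4 was about 51.6-fold lower (log2 change -5.69, SE 0.41, adjusted p = 0.000389), with a CMS50 mean of 4.09, and Klk1 and Klk1b3 changed by -3.27 and -3.04. These kallikreins belong to a family of near-identical genes, so which member each probe set reads is uncertain. Gtpbp4, a GTPase of ribosome assembly, was 19.4-fold lower at 7.26 ± 0.31 against 11.54 ± 0.10, and its 2 probe sets changed by -4.28 and -3.89. Slco1a1, an organic anion transporter, changed by -3.60, Slc7a12, an amino acid transporter, by -3.57, and Gc, the vitamin D binding protein, by -3.54. Rbp4, the retinol carrier, Coch (cochlin) and Tnfrsf11b (osteoprotegerin) changed by -3.23, -3.17 and -2.88. Adjusted p-values of these 10 falls ran from 0.000389 to 0.00919. Without CMS50 replicate 3 the changes of Slco1a1, Slc7a12, Gc, Rbp4, Coch and Tnfrsf11b were -4.67, -4.36, -4.28, -4.06, -3.79 and -3.47. Without CMS50 replicate 2 those of Slco1a1 and Slc7a12 were -2.99 and -2.92, and without CMS50 replicate 1 that of Gc was -2.94. Averaged over its probe sets, Gc changed by -2.48.

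Across all genes, 3211 of 10337 were called (31.1%), 2028 higher and 1183 lower in CMS50, and 603 of these changed at least 2-fold, 361 up and 242 down. The count was 1847 without vehicle replicate 2, 1677 without CMS50 replicate 1 and 1633 without CMS50 replicate 2, which also left 395 genes with a 2-fold change. CMS50 replicate 3 lay between the other CMS50 arrays and the vehicle arrays, with a median share of 0.566 of their response over 819 genes chosen without it, a measure added after the data were seen, and 3522 genes were called when it was left out. The RNA of the CMS50 kidneys also differed in a quality reading, the log2 difference between 3′ and 5′ control probe sets. For beta-actin it was 3.58 ± 0.0854 in CMS50, 3.17 ± 0.120 in CMS25 and 2.98 ± 0.155 in vehicle. For GAPDH the values were 0.816 ± 0.0622, 0.698 ± 0.209 and 0.542 ± 0.0286. Both readings gave a two-sided exact permutation p of 0.1 for CMS50 against vehicle, the smallest that 3 against 3 allows, and they move with every gene group described for CMS50.

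**Figure D1:**
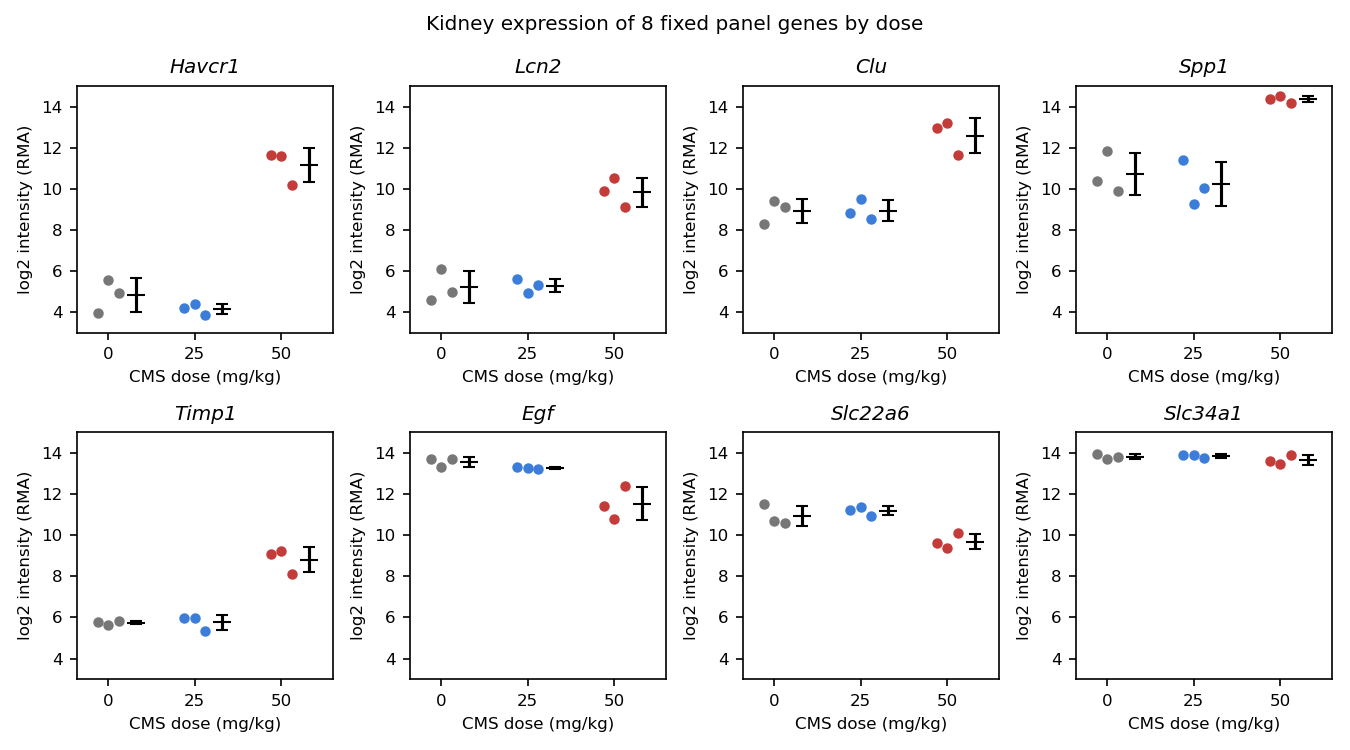
Log2 intensity (vertical axis) of 8 genes fixed before the data were examined, against the CMS dose in mg/kg (horizontal axis). Points are single rats, and the black dash with its bar is the mean ± SD of the 3 rats of a dose. Havcr1 lies at 4.83 in vehicle, 4.15 in CMS25 and 11.15 in CMS50, while the means of Slc34a1 stay between 13.66 and 13.85.

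Injury and proliferation genes rose together. Of 26 measured tubular injury markers, 20 rose and 1 fell (21 and 1 adjusted over the list alone), with a median change of 1.60 (camera adjusted p = 4.89e-09, and adjusted p = 0.323 with an estimated correlation). Of 37 measured cell cycle genes, from 46 on the array, 31 rose and 1 fell (33 and 1 adjusted over the list alone), with a median of 1.22. The intensity minimum uses the mean over all 9 arrays, so a gene dim in vehicle could pass by rising in CMS50. Shares of rises among measured genes may be raised by this. The proliferation marker Mki67 rose by 2.34, the phosphatase Cdkn3 by 2.09, the spindle protein Prc1 by 1.81 and the cytokinesis factor Ect2 by 1.79. This list had a camera adjusted p of 2.82e-11, and adjusted p = 0.369 with an estimated correlation. Among 19 apoptosis genes, 9 rose and 1 fell (10 and 1 adjusted over the list alone), led by Birc3 (1.27), Tnfrsf1a (1.21), Apaf1 (1.12) and Casp8 (1.10). Birc3 is an inhibitor of apoptosis, whereas Apaf1 and Casp8 activate caspases. Casp8 had 2 probe sets of nearly equal mean intensity (6.46 and 6.43), which changed by 1.10 and 0.66. The probe set was picked anew in each leave-out. Casp8 was at 0.60 without CMS50 replicate 1 and 0.59 without CMS50 replicate 2. These values may read the other probe set rather than an effect of 1 array. The list's camera adjusted p was 0.00438, and adjusted p = 0.323 with an estimated correlation. Of 9 necroptosis and inflammasome genes, 6 rose and 0 fell (also 6 and 0 adjusted over the list alone), among them the inflammatory caspase Casp4 (1.22) and the adaptor Pycard (0.74). That list was called at adjusted p = 0.00406, and adjusted p = 0.369 with an estimated correlation. Of 17 p53 targets, 7 rose and 0 fell (7 and 1 adjusted over the list alone), including the cell cycle inhibitor Cdkn1a (0.99, SE 0.13), but the list was not called by camera (adjusted p = 0.176), while fry, a rotation test of whether genes move one way on balance, called it higher (adjusted p = 0.0160).

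Genes of macrophages, antigen presentation and matrix also rose. Of 23 measured macrophage and myeloid markers, from 27 on the array, 20 rose and 0 fell (20 and 0 adjusted over the list alone), with a median of 1.22. The mannose receptor Mrc1 rose by 2.74, the lectin Clec4a3 by 1.91, and the complement C1q chains C1qb and C1qa by 1.69 and 1.63. The camera adjusted p was 1.88e-08, and adjusted p = 0.369 with an estimated correlation. All 6 called of 8 MHC class II genes rose (7 adjusted over the list alone), with RT1-Da 2.82-fold higher and Cd74, the invariant chain, 2.28-fold higher. The list was called at adjusted p = 0.00119, and adjusted p = 0.369 with an estimated correlation. Of 14 complement genes, 8 rose and 1 fell (9 and 1 adjusted over the list alone), with adjusted p = 0.00725, and adjusted p = 0.369 with an estimated correlation. Of 27 genes of cytokines, chemokines and the NF-kB pathway, 13 rose and 1 fell (14 and 3 adjusted over the list alone), with Ccl2, which attracts monocytes, at 1.55 and the adhesion molecule Icam1 at 1.53. This call (adjusted p = 0.0126, and adjusted p = 0.369 with an estimated correlation) ended with a minimum mean log2 value of 6 (adjusted p = 0.154). Of 25 interferon response genes, 13 rose and 0 fell (13 and 0 adjusted over the list alone). The immunoproteasome subunits Psmb8 and Psmb10 rose by 1.76 and 1.49, the GTPase Gbp2 by 1.72 and the transcription factor Irf1 by 1.42. The interferon list was called at adjusted p = 0.000369, and adjusted p = 0.369 with an estimated correlation.

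Fibroblast and matrix genes had 17 rises and 1 fall among 27 (19 and 1 adjusted over the list alone), with a median of 1.24. Timp1, an inhibitor of matrix proteases, rose by 3.07 (SE 0.28), fibronectin (Fn1) by 2.04 and the basement membrane collagen Col4a1 by 2.00. The list had a camera adjusted p of 3.99e-05, and adjusted p = 0.401 with an estimated correlation. Of 5 measured lymphocyte genes, 1 rose and 0 fell (1 and 0 adjusted over the list alone), and that list was not called by camera (adjusted p = 0.460) but called higher by fry (adjusted p = 0.0116). No neutrophil marker passed the intensity minimum.

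Genes of the nephron segments moved in both directions. In the proximal tubule, which reabsorbs most of the filtrate, 14 of 45 measured genes fell, 7 rose and the median change was -0.24 (17 fell and 7 rose adjusted over the list alone). Falls included Slco1a1 and the organic cation transporter Slc22a2 (-2.59, SE 0.51, and -3.27 without CMS50 replicate 3). The organic anion transporter Slc22a6 also fell, by 1.25, whereas the glucose transporter Slc2a2 rose by 2.15 (SE 0.27, adjusted p = 0.00215). The phosphate transporter Slc34a1 changed by -0.15 (95% interval -0.44 to 0.13, adjusted p = 0.378) and the endocytic receptor Lrp2 by 0.07 (-0.12 to 0.27, adjusted p = 0.567). The proximal tubule list was called lower (camera adjusted p = 0.0129, and adjusted p = 0.383 with an estimated correlation), but not by fry (adjusted p = 0.220). That call ended after cyclic loess scaling and without vehicle replicate 1 (largest adjusted p = 0.0682). In these arrays the macrophage median rose by 1.22 as given above. Of 6 candidate carriers of colistin uptake, 1 rose and 0 fell (1 and 0 adjusted over the list alone), and the list was not called (adjusted p = 0.439). The peptide transporter Slc15a2 missed the threshold (-0.80, SE 0.28, adjusted p = 0.0572, from 0.0132 to 0.188 over the alternatives), as did the carnitine transporter Slc22a5 (-0.24, SE 0.11, adjusted p = 0.138).

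Beyond the proximal tubule, 6 of 17 loop of Henle and distal tubule genes fell and 1 rose (7 and 1 adjusted over the list alone). The growth factor Egf fell by 2.04 (SE 0.33), the phosphatase inhibitor Ppp1r1a by 1.99 and the potassium channel Kcnj1 by 1.60. Umod (uromodulin) fell by 1.27 (SE 0.40, adjusted p = 0.0400). Its call was lost with only the 2 groups compared and in leave-outs of vehicle replicates 1, 2 and 3, CMS25 replicates 1, 2 and 3 and CMS50 replicate 1 (adjusted p over all alternatives from 0.00416 to 0.101), and its change was -0.71 without CMS50 replicate 2. The distal list was called lower at adjusted p = 0.00268, and adjusted p = 0.369 with an estimated correlation. In the collecting duct, 6 of 20 genes fell and 0 rose (6 and 0 adjusted over the list alone). The most negative was Slc4a1, the anion exchanger of acid-secreting intercalated cells, at -1.67 (SE 0.28). The collecting duct list had a camera adjusted p of 0.000209, and adjusted p = 0.383 with an estimated correlation, and did not pass fry (adjusted p = 0.114). Among 12 podocyte genes, 2 rose and 2 fell (2 and 2 adjusted over the list alone), with the transcription factor Wt1 at -1.36 and the adaptor Cd2ap at 0.69. The podocyte call (adjusted p = 0.0397, and adjusted p = 0.509 with an estimated correlation) did not hold with fry (adjusted p = 0.243) and ended in 8 of 19 alternatives, including those without vehicle replicates 1 and 3 and CMS50 replicates 2 and 3 (largest adjusted p = 0.0999). Endothelial genes, with 2 rises and 4 falls among 15 (2 and 4 adjusted over the list alone), were not called as a list (adjusted p = 0.291).

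Metabolic lists were called lower, apart from glycolysis and cholesterol synthesis, which were not called. Of 36 genes of fatty acid oxidation and the peroxisome, 15 fell and 0 rose (15 and 0 adjusted over the list alone), with Ehhadh, a peroxisomal beta-oxidation enzyme, at -1.25 and Etfdh, which passes electrons from fatty acid oxidation to the respiratory chain, at -0.88. This list was called at adjusted p = 6.9e-06, and adjusted p = 0.323 with an estimated correlation. Of 41 oxidative phosphorylation genes, 11 fell and 0 rose (9 and 0 adjusted over the list alone). The succinate dehydrogenase subunits Sdhd and Sdhc fell by 0.65 and 0.45, with the list at adjusted p = 4.32e-07, and adjusted p = 0.369 with an estimated correlation. Drug metabolism and efflux genes had 12 falls and 3 rises among 31 (14 and 3 adjusted over the list alone), with the glutathione transferases Gsta1 and Gsta3 at -2.02 and -1.57 and the cytochrome Cyp1b1 at 1.40. The list was called lower at adjusted p = 2.19e-05, and adjusted p = 0.369 with an estimated correlation. In the renin, vasopressin and hormone axis list, 3 of 11 genes fell and 0 rose (3 and 0 adjusted over the list alone), led by Kl (klotho, -1.20, SE 0.25). That list had adjusted p = 0.00438, and adjusted p = 0.323 with an estimated correlation.

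Stress genes did not move as 1 block. Among 20 antioxidant enzymes, 7 fell and 5 rose (9 and 5 adjusted over the list alone), with Msra, a methionine sulfoxide reductase, at -1.29, the superoxide dismutases Sod1 at -0.77 and Sod3 at 1.19. The list was called lower at adjusted p = 0.0467, and adjusted p = 0.369 with an estimated correlation, but that call ended in 13 of 19 alternatives, and 6 of those 13 left out an array: vehicle replicates 1 and 3, CMS25 replicates 1, 2 and 3 and CMS50 replicate 1 (largest adjusted p = 0.151). Targets of the transcription factor Nrf2 had 6 rises and 8 falls among 25 (7 and 8 adjusted over the list alone) and were not called (adjusted p = 0.593). Of 17 heat shock genes, 5 fell and 0 rose (5 and 0 adjusted over the list alone), with the chaperone Hsph1 at -1.05 (SE 0.13) and the co-chaperone Chordc1 at -0.55. That list was called at adjusted p = 0.000542, and adjusted p = 0.323 with an estimated correlation. Lysosome and autophagy genes had 15 rises and 4 falls among 34 (16 and 5 adjusted over the list alone), with the protease cathepsin D (Ctsd) at 1.44 and progranulin (Grn) at 0.93. The lysosome call (adjusted p = 0.0290, and adjusted p = 0.383 with an estimated correlation) ended without vehicle replicate 3 (adjusted p = 0.0675). The unfolded protein response list, with 3 rises and 3 falls among 27, was not called (adjusted p = 0.176), nor were metallothioneins and metal handling (2 and 2 of 9, adjusted p = 0.796). Glycolysis (2 rises and 1 fall among 15, adjusted p = 0.593) and cholesterol synthesis (4 rises and 1 fall among 20, adjusted p = 0.818) were not called either. Adjusted over the list alone, these last 4 lists had 3 and 3, 3 and 2, 2 and 1, and 4 and 1 rises and falls. The medians of the metallothionein and cholesterol lists were positive (0.06 and 0.02) while their tests pointed lower.

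Of lists for other tissue in the sample, adipose genes had 2 falls among 7 (2 adjusted over the list alone) and were not called (adjusted p = 0.199). Circadian genes, with 5 rises and 4 falls among 17 (6 and 5 adjusted over the list alone), were not called in either direction (adjusted p = 0.697). In all, 21 of 32 lists were called with the preset correlation, 11 higher and 10 lower, and 0 with an estimated correlation (smallest adjusted p = 0.323). fry called 20 lists, 18 of them also called by camera, and those it left out were the proximal tubule, collecting duct and podocyte lists. The p53 and lymphocyte lists were called by fry and not by camera. Lists with under 5 measured genes were not tested. Both measured erythrocyte genes were called lower, 1 of 4 adrenal genes was called higher, and 0 of 2 skeletal muscle and 0 of 2 Y-linked genes were called.

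**Figure D2:**
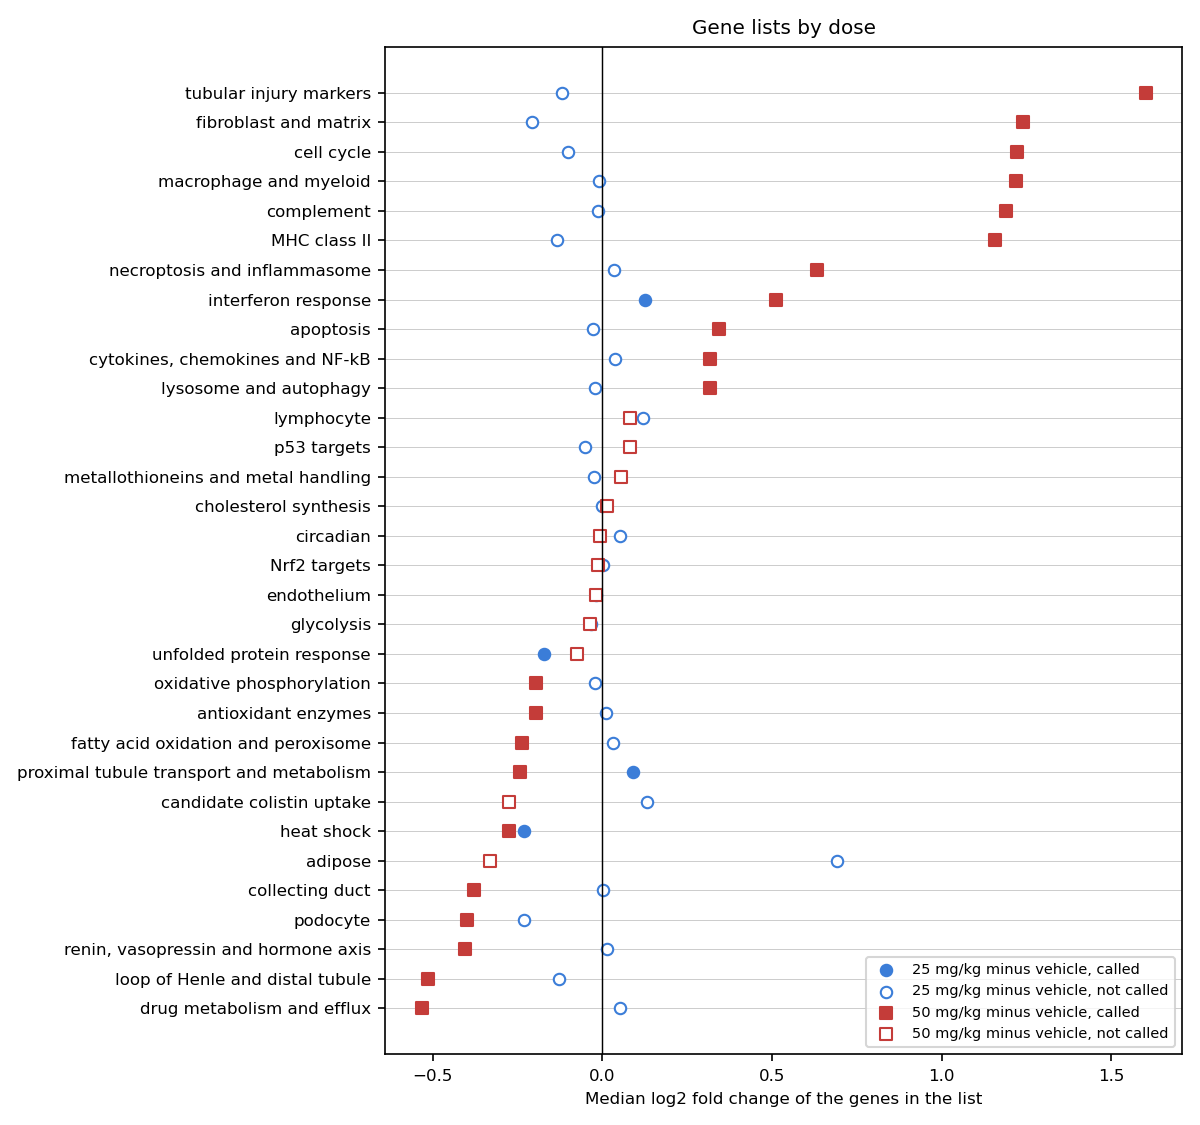
Median log2 fold change (horizontal axis) of the genes of each list with at least 5 measured genes (vertical axis). Circles are CMS25 minus vehicle and squares CMS50 minus vehicle, and the lists were fixed before the data were examined. Filled symbols were called by camera with a preset correlation. Medians at CMS50 run from positive values in injury markers (1.60) to negative values in drug metabolism (-0.53), and those at CMS25 run from -0.23 in heat shock genes (called) to 0.69 in adipose genes (not called).

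The lower dose was compared with vehicle to ask what 25 mg/kg changed. No single gene was called. Havcr1 was at 4.15 ± 0.26 in CMS25 against 4.83 ± 0.81 in vehicle (log2 change -0.68, 95% interval -1.72 to 0.36, adjusted p = 0.883). Lcn2 changed by 0.07 (-0.89 to 1.03), Clu by 0.01 (-0.97 to 1.00) and Spp1 by -0.47 (-1.76 to 0.82), so rises of up to 1.03, 1.00 and 0.82 in Lcn2, Clu and Spp1 stay inside the intervals, but in Havcr1 only rises of up to 0.36. Cdkn1a (-0.22), Egf (-0.31), Timp1 (0.02), Umod (-0.03), Slc34a1 (0.03), Slc22a6 (0.25), Slc15a2 (-0.21), Slc22a5 (0.20) and Lrp2 (-0.07) did not pass the test either. limma called 0 of 10337 genes at the threshold (smallest adjusted p = 0.523), 0 of them under every alternative tried, and 604 at an unadjusted p under 0.05, where chance alone gives 517.

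With the preset correlation, camera called 4 lists at 25 mg/kg without any called member. However, 7 of 10 splits of the same 6 arrays, the real one included, gave at least 4 lists. The number of lists called is therefore no sign of a dose effect. Heat shock genes were lower, with a median of -0.23 over 17 genes (camera adjusted p = 2.06e-07, and adjusted p = 0.167 with an estimated correlation), and 7 of them were lower adjusted over the list alone. Hsph1 was at 9.28 ± 0.14 against 9.93 ± 0.24, and Chordc1 at 8.83 ± 0.09 against 9.40 ± 0.12. Unfolded protein response genes were lower, with a median of -0.17 over 27 genes (adjusted p = 0.000348, and adjusted p = 0.167 with an estimated correlation) and 0 called adjusted over the list alone. Both lists also passed fry (adjusted p = 0.0367 and 0.0480), and the interferon and proximal tubule lists that follow did not (adjusted p = 0.937 for both). Interferon response genes (median 0.12, adjusted p = 0.00297, and adjusted p = 0.774 with an estimated correlation) and proximal tubule genes (median 0.09, adjusted p = 0.00979, and adjusted p = 0.774 with an estimated correlation) were higher, with 0 called members adjusted over the list alone. Both of these calls ended without vehicle replicate 2 and without CMS25 replicate 1, the interferon call also without CMS25 replicate 2, and the proximal tubule call also without CMS25 replicate 3 or with no intensity minimum (largest adjusted p = 0.120 and 0.142). Circadian genes were not called as a list (adjusted p = 0.263), although 4 were higher and 2 lower adjusted over the list alone.

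The doses were then compared with each other. Injury genes were higher in CMS50 than in CMS25. Havcr1 was about 128-fold higher (log2 change 7.00, SE 0.46, adjusted p = 0.000261) and Lcn2 23.4-fold higher. Serpina3n, an acute-phase protease inhibitor, was about 24.3-fold higher, Spp1 17.4-fold and the fibrinogen chain Fgb about 14.0-fold. The log2 change of Serpina3n (4.60, SE 1.02) was 5.69 without CMS50 replicate 1 and 3.47 without CMS50 replicate 2. The CMS25 means of Havcr1 (4.15), Serpina3n (3.64) and Fgb (3.97) and the CMS50 mean of Klk1c4 (4.09) lay below the intensity minimum, so these folds are approximate. Klk1c4 was about 46.9-fold lower, Gtpbp4 18.9-fold lower, Slco1a1 10.8-fold lower and Hbb, a haemoglobin gene with near-identical copies, 8.79-fold lower. The log2 change of Slco1a1 (-3.44, SE 0.73) was -2.82 without CMS50 replicate 2 and -4.50 without CMS50 replicate 3, and that of Hbb (-3.14, SE 0.59) was -2.31 without CMS50 replicate 2. Cyp2c11, a male-predominant rat cytochrome, changed by -3.82 (SE 1.07, adjusted p = 0.0269), with CMS50 rats spread over an SD of 2.59, and by -3.03 without CMS50 replicate 1 and -5.32 without CMS50 replicate 3. Its call was lost with only the 2 groups compared and without CMS25 replicate 1, 2 or 3 or CMS50 replicate 1 or 2 (adjusted p over all alternatives from 0.000335 to 0.0977).

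In total, 3128 genes were called between the doses, 2153 higher and 975 lower in CMS50, with 562 changed at least 2-fold (372 up, 190 down, and 368 in total without CMS50 replicate 2). After cyclic loess scaling the split was 1746 higher and 1223 lower. The total was 2006 without CMS25 replicate 3, 1702 without CMS50 replicate 1 and 1522 without CMS50 replicate 2. Cell cycle genes (32 rises and 1 fall among 37), macrophage genes (19 and 0 among 23) and matrix genes (22 and 1 among 27) rose, and their adjusted p-values were 5.44e-12, 6.46e-08 and 1.67e-06. Adjusted over the list alone, these counts were 34 and 1, 19 and 0, and 23 and 1. Each of these lists had adjusted p = 0.365 with an estimated correlation. Proximal tubule genes had 18 falls and 6 rises among 45 (21 and 6 adjusted over the list alone), called at adjusted p = 0.000428, and adjusted p = 0.365 with an estimated correlation, but not by fry (adjusted p = 0.0511). Slc22a5 was lower by 0.44 (SE 0.11), although its call was lost without CMS25 replicate 1 or 2 or CMS50 replicate 1 or 2 (largest adjusted p = 0.0714), while Slc34a1 (-0.18) and Lrp2 (0.14) were not called. Heat shock genes were not called between the doses, with 2 rises and 2 falls among 17 (2 and 0 adjusted over the list alone, adjusted p = 0.427). In all, 20 of 32 lists were called with the preset correlation, 11 higher and 9 lower, and 0 with an estimated one (smallest adjusted p = 0.365). fry called 18 lists, 16 of them also called by camera. It left out the proximal tubule, distal tubule, collecting duct and adipose lists, and it alone called p53 targets and the unfolded protein response (adjusted p = 0.0107 and 0.0151). The beta-actin quality reading given above moved with these groups, at 3.58 ± 0.0854 in CMS50 and 3.17 ± 0.120 in CMS25.

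Across the 3 doses, 2903 genes differed by the limma F test. Response beyond a straight dose line, tested as CMS50 minus 2 times CMS25 plus vehicle, was called in 46 genes, 41 above the line and 5 below. Adamts1 (3.59 on the log2 scale, adjusted p = 0.0281), Akr1b8 (2.93, adjusted p = 0.0281) and Cdkn1a (1.42, adjusted p = 0.0359) were among those above it. Akr1b8 had a mean log2 value of only 5.14 over the 9 arrays, near the intensity minimum of 5. Small changes of dim probe sets are compressed, so a small change at 25 mg/kg could be missed and its bend is uncertain. Genes called at any dose numbered 1183 without CMS50 replicate 1 and 1112 without CMS50 replicate 2. The 46 became 1078 without CMS50 replicate 3, and 0 without vehicle replicate 2 or CMS25 replicate 3. It was 2 without vehicle replicate 1, 9 without vehicle replicate 3, 1 without CMS25 replicate 2, 9 without CMS50 replicate 1 and 14 without CMS50 replicate 2. Genes called in CMS50 against both other groups numbered 1659 higher and 765 lower, where independent lists would share 422 and 112, and 0 were called in opposite directions. Simulated unchanged groups shared 0 genes, but almost no gene is called without a change, so this sets no chance value for the overlap, and part of the excess may come from the shared CMS50 arrays. The covariance of these changes was 0.260, against 0.0173 for the simulated groups. Across genes, changes at 25 and 50 mg/kg against vehicle had a Pearson correlation of 0.205, and genes are not independent replicates. Unchanged groups simulated against the same 3 vehicle arrays gave 0.496. These Pearson values are not comparable, because the large changes in CMS50 widen 1 contrast and lower the correlation, while simulated groups have no change. The covariance was 0.0195 against a simulated mean of 0.0172, a difference of 0.00237. The spread of the simulated draws is not given, so this difference decides nothing. Covariance was 0.00919 without CMS25 replicate 1, 0.0333 without CMS25 replicate 3 and 0.0304 without vehicle replicate 1.

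**Figure D3:**
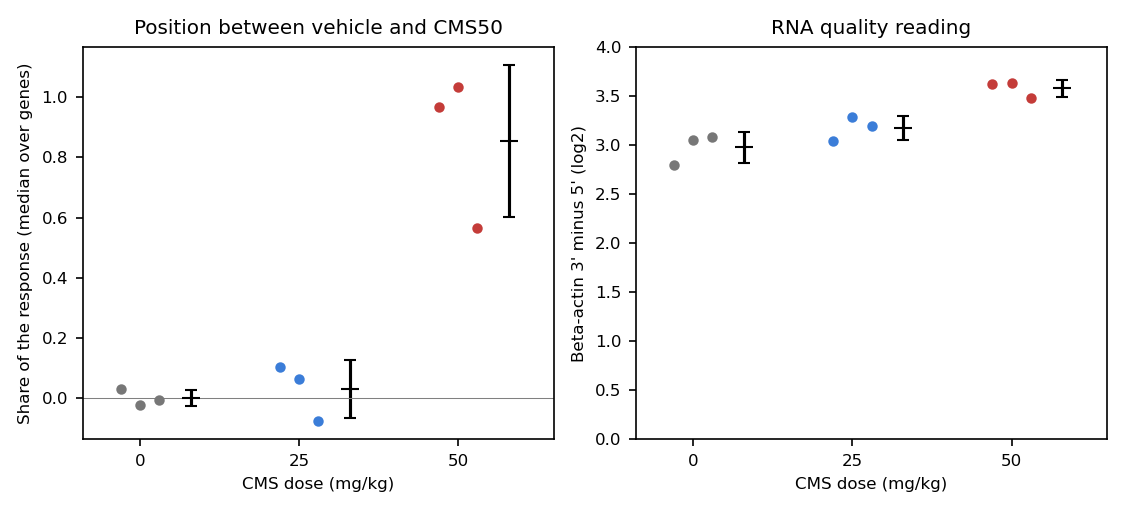
Left, the share of the CMS50 response in each array (vertical axis, 0 at the vehicle mean and 1 at the mean of CMS50 replicates 1 and 2, median over 819 genes), and right, the log2 difference of 3′ and 5′ beta-actin probe sets, both against the CMS dose in mg/kg. Points are single rats, and the black dash with its bar is the mean ± SD. CMS50 replicate 3 lies at 0.566 and the highest vehicle or CMS25 array at 0.103.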

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

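Tests of RNA quality and of cell composition, the share of the response in each array and the counts of other splits for genes at 25 mg/kg were chosen only after the result was seen, while the counts of splits for the other results were planned. Probe sets outside the gene-level comparison also differed between CMS50 and vehicle. Of 4028 tested probe sets without a single named gene, 929 were called by limma, 485 higher and 444 lower, and 168 changed at least 2-fold. Probe set 1397769_at rose by 3.80 on the log2 scale and 1370892_at by 3.77, with adjusted p = 0.000243 for both. Probe sets 1398687_at and 1381233_at changed by -3.33 (adjusted p = 0.00520) and -3.56 (adjusted p = 0.00945).

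Control probe sets gave a further signal. The 3′ minus 5′ difference was 0.60 higher in CMS50 than in vehicle for beta-actin and 0.27 higher for GAPDH, with a two-sided exact permutation p of 0.1 for each, the smallest that 3 against 3 arrays allow. RNA degradation could account for the many genes that differ if the response of an array follows this difference. With shares scaled to CMS50 replicates 1 and 2, CMS25 arrays had 0.301 (SD 0.184) of the beta-actin shift and 0.549 (SD 0.738) of the GAPDH shift. Their mean response share was 0.0300 (SD 0.0951), a gap to beta-actin within 2 times the combined SD. That margin is wider than the beta-actin share itself, so even arrays without any response would have stayed within it. The comparison could therefore not have excluded degradation. CMS25 replicates 1, 2 and 3 had beta-actin differences of 3.05, 3.28 and 3.19 and response shares of 0.103, 0.0642 and -0.0776, while CMS50 replicate 3 had 0.772 of the beta-actin shift and 0.566 of the response. The GAPDH difference of CMS25 replicate 2 (0.913) lay above those of the CMS50 arrays (0.766 to 0.886), which goes against degradation but rests on 1 array. Degradation and the dose itself cannot be told apart here, because both control readings vary too much between the CMS25 arrays to decide.

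In CMS50, camera with the preset correlation called proximal tubule genes lower as a list, with 14 falls and 7 rises, while 20 of 23 macrophage genes rose. The proximal tubule list was not called by camera with an estimated correlation (adjusted p = 0.383) or by fry (adjusted p = 0.220). Its call also ended after cyclic loess and without vehicle replicate 1 (largest adjusted p = 0.0682). Loss of proximal tubule cells may lower all of their genes by a like amount. Yet 7 proximal tubule genes were called higher, which argues against loss as the whole cause for those 7 genes. This comparison and the next were chosen with the counts and medians already known. They therefore describe the pattern and are not an independent test. A lower share of proximal tubule RNA would raise markers of other cell types alike. However, 20 of 23 macrophage markers rose (median 1.22), while 6 of 20 collecting duct markers fell and 0 rose (median -0.38). That difference of medians, 1.60, argues against such a shift as the whole cause. The SE of 0.170 computed across genes is that of the difference of means and takes genes as independent. It does not measure the spread between rats. More macrophages, higher expression in the same number of cells, and an effect of the dose on tubule genes stay open, because whole kidneys hold all cell types together.

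Other splits of the same arrays were counted for each result. For CMS25 against vehicle, all 10 splits gave at least the real 0 genes and 0 genes with a 2-fold change (highest other 1 and 1), and 7 of 10 gave as many lists as the real 4 (highest other 8). For CMS50 against vehicle, 1 of 10 splits, the real one, gave 3211 genes, 603 with a 2-fold change and 21 lists, and the highest others gave 0, 0 and 17. For CMS50 against CMS25, 1 of 10 splits, the real one, gave 3128 genes, 562 with a 2-fold change and 20 lists, and the highest others gave 0, 0 and 16. With 10 splits, no share under 0.05 can be reached. For any dose, 1 of 100 splits reached the real 2903 genes, so chance was excluded for a difference among the doses, but the highest other split (2841) kept the 3 CMS50 arrays together and mixed vehicle with CMS25, so this count reads CMS50 against the rest and says nothing of CMS25 against vehicle. For departure from a straight dose line, 3 of 100 splits gave as many as the real 46, but splits that part the CMS50 arrays widen the spread within groups, so this count mainly reads whether those arrays stay together and does not exclude chance for the bend itself. Leaving out vehicle replicate 2 or CMS25 replicate 3 gave 0 genes, CMS25 replicate 2 gave 1 and vehicle replicate 1 gave 2. The highest other split gave 3961 genes with the 3 CMS50 arrays as its middle group, which points to the structure of the samples.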

How the results depend on the processing

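No alternative reported here was chosen only after the result was seen. Of 199 named gene and comparison pairs, 179 were called, all 179 kept their direction, 143 kept their call under every alternative, 17 lost it only when an array was left out and 19 under at least 1 other alternative. At 25 mg/kg, gene lists called went from 4 to 7 after cyclic loess, 2 with fry and 0 with an estimated correlation, which also left 0 lists for CMS50 against vehicle and 0 for CMS50 against CMS25. Departures from a straight dose line went from 46 genes to 78 with an intensity trend and robust fitting, 212 with array weights and 74 with each probe set tested. Leaving out 1 array at a time gave 1633 to 3522 genes (395 to 808 with a 2-fold change) for CMS50 against vehicle. For CMS50 against CMS25 it gave 1522 to 3506 (368 to 801), for departures 0 to 1078, for any dose 1112 to 3181, and for the covariance 0.00919 to 0.0333. An arm with 2 arrays has fewer samples, and otherwise the cause was not tested. Uncalled changes at 25 mg/kg crossed 0: Clu was at -0.036 with array weights and ran from -0.31 to 0.25 over leave-outs, Lcn2 from -0.25 to 0.51, Slc34a1 from -0.027 to 0.092, Spp1 from -1.05 to 0.11, Timp1 from -0.085 to 0.23 and Umod from -0.093 to 0.023. With the replicate block, 2865 genes were called for CMS50 against vehicle, 2857 for CMS50 against CMS25 and 0 for CMS25 against vehicle. Correlations of same-numbered arrays ran from -0.183 to 0.263, with 3 of 9 above 0.1, and 4 of 9 arrays matched their own number best. These values gave no clear sign that the numbers pair the rats, but 3 arrays per dose are too few to exclude it. Dim probe sets lie near background, where RMA compresses changes.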

Other observations

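Tests of gene families, of the share of each gene's change in CMS50 replicate 3, of the clock score and of list means per array were chosen only after the result was seen. Ribosomal protein genes were higher in CMS50 kidneys. Of 29 measured genes with symbols starting Rpl, for the large subunit, 27 were called higher than in vehicle and 0 lower, with a median of 0.48. Of 20 genes starting Rps, for the small subunit, 11 were higher and 0 lower, with a median of 0.40. The medians were 0.45 and 0.37 with array medians set alike, and 0.56 and 0.42 after cyclic loess. Camera with a preset correlation gave adjusted p = 6.62e-09 for Rpl and 0.0168 for Rps, among 10 called of 173 families sharing a symbol stem, and adjusted p = 0.823 for both with an estimated correlation.

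Genes with large changes differed in how far CMS50 replicate 3 followed the other CMS50 arrays. Against a median share of 0.566 over the 819 response genes, Gtpbp4 had 0.881 of its log2 change there, Klk1c4 0.855, Havcr1 0.786 and Slco1a1 0.315. These 4 were chosen after their values were seen. On the log2 scale, rising response genes had a median share of 0.612 in that array and falling ones 0.474. On the linear scale those medians were 0.473 and 0.619, so their order depends on the scale. Shares of the 4 genes were not taken on the linear scale.

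Some clock genes were called in CMS50, while the circadian list was called at neither dose, and the genes named here were chosen after their values were seen. In CMS50 against vehicle, Bmal1 fell by 1.55, Cry1 by 0.98 and Npas2 by 1.01, and Nr1d1 rose by 1.06 and Per3 by 1.02. In CMS25, where no gene was called, Bmal1 was at -0.89 and Nr1d1 at 1.18 relative to vehicle. A score, the mean of 10 clock genes driven through E-boxes minus that of 5 driven through ROR elements, was 0.201 ± 0.323 in vehicle, 1.31 ± 0.987 in CMS25 and 1.36 ± 0.365 in CMS50 (n = 3 each). A clock change that follows tubular injury may leave CMS25 near vehicle, and the CMS25 shift was 0.957 of the CMS50 shift, but CMS25 replicate 1 (0.175) lay within the vehicle arrays, so this stays undecided. Chance was not excluded, with a two-sided exact permutation p of 0.0595 over 84 splits of 3 vehicle from 6 CMS arrays. The labels give no time of kill, which could differ between groups and was not tested.

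The heat shock list was called lower at both doses with a preset correlation, but not with an estimated one (adjusted p = 0.167 for CMS25 and 0.323 for CMS50), with 0 members called over all genes at CMS25 and 5 at CMS50. Both comparisons use the same 3 vehicle arrays, so these calls are not independent of each other. Between the doses the list was not called (camera adjusted p = 0.427). The mean of the list was 9.18 ± 0.0670 in vehicle, 8.92 ± 0.0496 in CMS25 and 8.88 ± 0.0487 in CMS50 (two-sided exact permutation p = 0.0119 for 3 vehicle against 6 CMS arrays, the smallest that 84 splits allow). The list was picked for this test because it had been called at both doses, so the p is not independent evidence. The unfolded protein response list was at 8.36 ± 0.0581, 8.20 ± 0.0104 and 8.36 ± 0.0420 (two-sided exact permutation p = 0.298).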
